A study of Mus musculus with 7 samples.

How the data were processed

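Data of 4 RNA libraries of cultured cortical neurons (2 control, 2 KCl) and 3 H3K9me3 ChIP libraries of hippocampus (1 home cage, 2 enriched cage) were analysed from the deposited processed files. Groups were taken from the sample titles and protocols in the labels.

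For each RNA library the authors deposited whole-number read counts of the inclusion and the skipping form of splicing events of 5 types, per the file headers: skipped or cassette exons, mutually exclusive exons, retained introns and alternative 5′ and 3′ splice sites. The same tables hold p-values and FDRs that the authors deposited for KCl against control within a replicate number. For each ChIP library the authors deposited coverage as a signal track scaled to the reads of the library. Every value in it is a whole multiple of 1 step (tolerance 0.01), which gave the fragments behind it. CASAVA 1.7, BWA 0.7.12, MACS2, TopHat2 and the build mm10 are named in the submitters' processing notes, which do not say which tool made which file. The event counter, its annotation, read filters and handling of duplicates are not given in the sources used here.

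Event starts were converted to count from 1. The tables do not give the flanking exons, so events that share coordinates cannot be told apart: 2634 of 19447 rows of replicate 1 and 3120 of 22703 rows of replicate 2 did. The 11814 events with unique coordinates in both tables were used, and those with a mean of at least 1 read of each form were tested for splicing. Effective lengths are not given either, so the inclusion read share is the inclusion reads in percent of inclusion and skipping reads, not a percent spliced in, and is compared only for the same event between libraries. Splicing was tested with edgeR 4.0.16 (R 4.3.3), quasi-likelihood, on the counts of both forms, with a term per library, the form and the form in KCl. Event levels (both forms summed) and the best-covered event of each gene were tested with edgeR's quasi-likelihood test, with a minimum mean of 1 read. Their model held an intercept and KCl only, and library sizes were scaled by TMM (trimmed mean of M values). limma 3.58.1 and DESeq2 1.42.0 were run as alternatives. Benjamini-Hochberg adjustment was used throughout, with a threshold of 0.05.

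Fragment positions were recovered from the steps of the coverage, with fragment lengths of 285, 207 and 238 bases in the home cage, enriched replicate 1 and enriched replicate 2. The tracks carry no strand, so at most 2 fragments per start were kept. They were counted by midpoint over 34614 gene models of GRCm38.p6, which is the build mm10, and over 10 kb windows, with a mean of at least 20 fragments. Libraries were scaled by the median ratio over windows in the lower 75% of mean signal, and limma with voom weights was used. Enrichment of a gene class is the mean of fragments per kb over its genes, divided by the library's median over 10 kb windows. Intervals of counts are exact Poisson, and intervals of ratios come from exact binomial intervals of the counts. Those of a gene class are Poisson intervals of its pooled fragments, scaled to the mean over genes. A fragment counts once for each gene model it falls in. The design had foreseen limma for gene values of RNA and read positions for ChIP; the files held counts and coverage, and the tests that these need were used.

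The items named were set by a rule written before the data were examined: up to 10 per direction past the threshold with groups that do not overlap, or, with fewer than 10 passing, the 10 per direction with the smallest unadjusted p; Nrxn2 and Nrxn3; and the leading members of each list. Some items that the rule names are not reported here. For H3K9me3 a mean of 50 fragments was required and unnamed gene models were left out. The 23 gene lists, named with their results in the text, were fixed at the same time, as were the tests and most alternatives. Set tests were fry and camera. limma on counts with other pseudocounts, DESeq2 for levels, events of equal coordinates summed, and events with reads of both forms were added as alternatives after the data were examined. Alternatives set beforehand were a replicate block, other filters and pseudocounts, other scalings, thinning, other windows and minimums, and leaving out each library. Other versions were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

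The fits were tested on simulated data with 200 changed items each. For splicing at a dispersion of 0.09, close to the 0.0941 of these libraries, 22.1% of events changed by 3 on the log2 odds scale and 0% of those changed by 1.5 were recovered, over 9515 and 9498 events. For gene levels, 4-fold changes were recovered in 87.5% at a dispersion of 0.05 and in 2.5% at 0.3, where these libraries had 0.153. For H3K9me3 over genes at a dispersion of 0.02, 15.8% of 2-fold and 97.6% of 4-fold changes were recovered, with 2 and 12 false calls. The dispersion of the ChIP libraries was not estimated, so these rates need not hold for them. Median event depth was 58 reads in control replicate 1, 59 in KCl replicate 1, 79 in control replicate 2 and 73 in KCl replicate 2. Mitochondrial fragments entered none of the comparisons over genes, windows or gene classes.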

Results

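RNA was sequenced from mouse primary cortical neurons, prepared from ICR embryos at day 16 and kept in culture to day 11. The neurons were exposed for 10 min to a buffer with 50 mM KCl, which depolarizes them, or to a control buffer with NaCl in its place, and were harvested 24 h later. There were 2 control and 2 KCl libraries. Reads assigned to splicing events came to 3566066 in control replicate 1, 3643165 in KCl replicate 1, 5385345 in control replicate 2 and 4666850 in KCl replicate 2. Chromatin carrying H3K9me3, a histone mark of silenced regions, was sequenced from the hippocampus of 3-month-old C57BL/6 mice. The 2 enriched libraries came from mice housed for 24 h in an enriched cage and then for 1 week in a home cage, and 1 library came from home-cage mice. They held 6187183 fragments for the home cage, 13008585 for enriched replicate 1 and 8058257 for enriched replicate 2. The labels do not say whether replicates are separate cultures or animals, so the p-values measure only the spread between these samples. Counting intervals below are at 95% and cover counting error only.

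The RNA libraries address whether a brief depolarization changes splicing a day later. In Pkm, which codes for pyruvate kinase, the choice between mutually exclusive exons on chromosome 9 (59675029 to 59675195 and 59675568 to 59675734, mm10) gave an inclusion read share of 67.3% ± 6.12 (SD, n = 2) in control and 18.96% ± 11.1 in KCl. Which exon of a mutually exclusive pair counts as inclusion was not established here, so the shares of such events do not say which exon rose. An alternative 3′ splice site of Synj1 (chromosome 16, 90973910 to 90974075) had a share of 3.07% ± 0.79 in control and 40.8% ± 14.2 in KCl, a log2 odds ratio of 4.40 (SE 0.77). A cassette exon of Ank2 (chromosome 3, 126963383 to 126963481) had 73.4% ± 1.29 in control and 19.6% ± 19.3 in KCl, a log2 odds ratio of -3.84 (SE 0.82). No event passed edgeR's test without a replicate block. Of 10088 events in 5503 genes, edgeR's quasi-likelihood test called 0 after Benjamini-Hochberg adjustment, with a smallest adjusted p of 0.0977. At an unadjusted p under 0.05 there were 929 events, 428 with higher and 501 with lower inclusion in KCl, against 504 expected by chance. DESeq2 called 11 and limma called 0. With the replicate number as a block edgeR called 167 (61 higher, 106 lower), but the labels do not say what a number shares. The shares of the groups did not overlap in 40.7% of events, against 33.3% by chance with 2 libraries per group.

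The other events with the smallest p among those whose groups did not overlap were cassette exons except where stated; each share is given in control and then in KCl, ± SD of 2 libraries. Higher shares in KCl were measured in Crim1 (72.9% ± 4.5 and 97.7% ± 0.05), Dst (42.6% ± 8.18 and 88.4% ± 4.46), Erc1 (26.1% ± 3.07 and 81.1% ± 17.1), Sbf1 (32.2% ± 14.2 and 83.7% ± 7.56), Myo5a (4.04% ± 1.73 and 35.4% ± 15.7) and Maoa (85.9% ± 0.31 and 100% ± 0). Ptprf had a pair of such exons, at 93.9% ± 3.33 and 99.8% ± 0.29 and at 62.7% ± 1.1 and 92.7% ± 5.74, and mutually exclusive exons of Pdlim7 stood at 82.6% ± 4.71 and 99.6% ± 0.52. Lower shares were measured in Nckap1 (17.5% ± 5.46 and 1.24% ± 1.39), Ehbp1 (97.9% ± 2.99 and 59.3% ± 9.48), Bin1 (93.8% ± 1.82 and 53.0% ± 25.1), Map6 (97.45% ± 0.67 and 62.9% ± 32.6) and Gapvd1 (59.5% ± 4.89 and 11.7% ± 9.62). Overlapping forms of the same Atp2b4 exon stood at 84.1% ± 5.07 and 31.9% ± 7.69 and at 81.1% ± 7.33 and 31.6% ± 8.93, and mutually exclusive exons of Dlgap4 at 72.0% ± 7.95 and 20.9% ± 11.6. The KCl libraries lay far apart in Map6 and Bin1. Their adjusted p lay between 0.0977 and 0.114 (edgeR). Cassette exons made up 765 of the 929 events at an unadjusted p under 0.05, and 6177 of the 10088 tested.

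**Figure D1:**
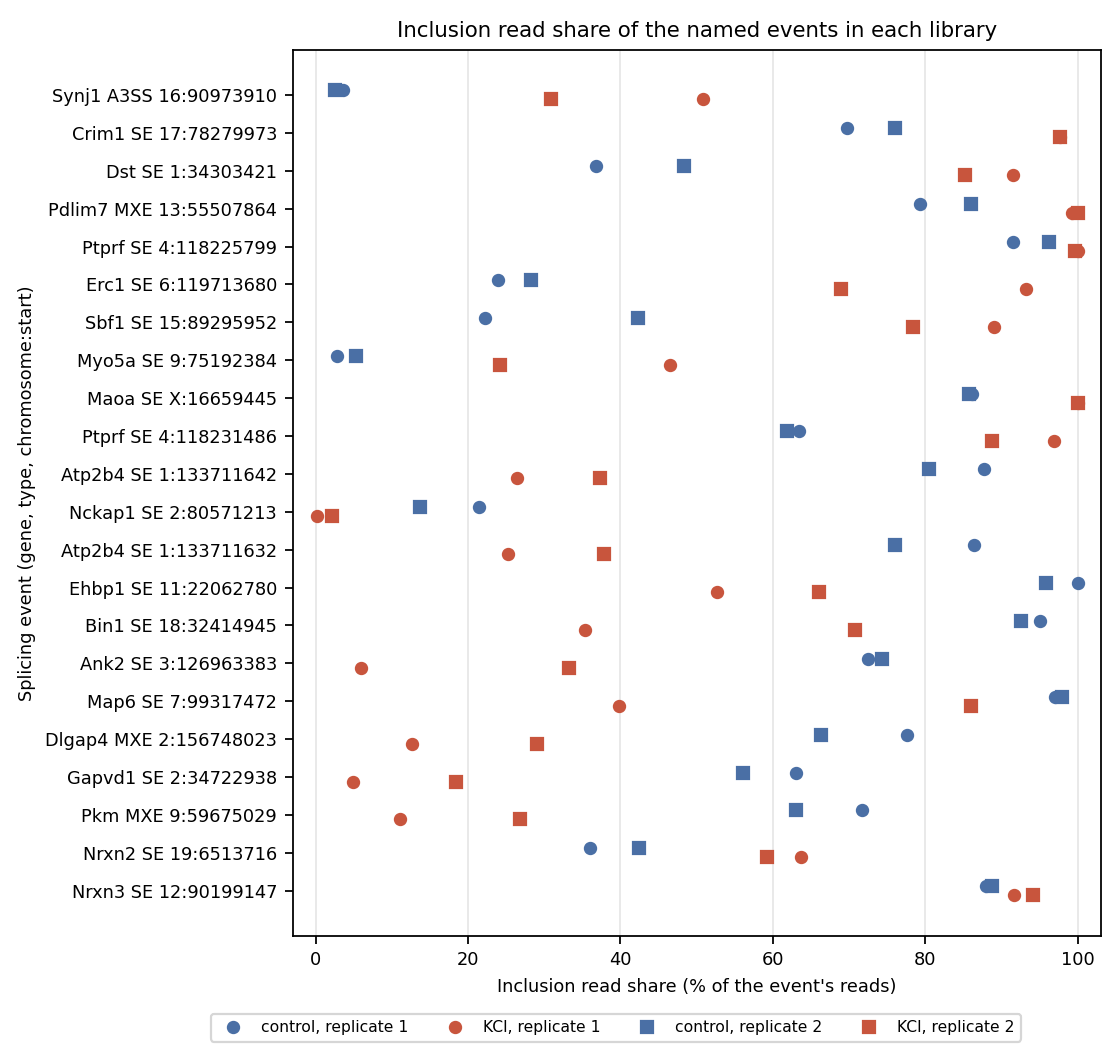
Inclusion read share, in percent of each event's reads, of the named events and of the 90-base exons of Nrxn2 and Nrxn3; each point is 1 library, circles are replicate 1 and squares replicate 2, blue is control and red KCl. In the Pkm event the KCl points average 18.96% and the control points 67.3%.

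Nrxn2 and Nrxn3, which code for cell adhesion molecules of the synapse, were chosen before the data were examined. The 90-base exon of Nrxn2 on chromosome 19 (6513716 to 6513805) had an inclusion read share of 39.2% ± 4.54 (SD, n = 2) in control and 61.5% ± 3.17 in KCl, a log2 odds ratio of 1.31 (SE 0.64) with an unadjusted p of 0.0526 and an adjusted p of 0.544 in edgeR's quasi-likelihood test, so it did not pass. The 90-base exon of Nrxn3 on chromosome 12 (90199147 to 90199236) had 88.3% ± 0.58 and 92.9% ± 1.71 (edgeR adjusted p 0.842). A Nrxn2 exon at 6488784 had a lower share in KCl, with 50.5% ± 3.42 in control and 17.1% ± 5.55 in KCl (edgeR adjusted p 0.328).

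Among the gene lists fixed before the data were examined, 0 events were called over all events tested by edgeR. Adjusted over the list alone, 10 of 57 events were called among other synaptic adhesion and guidance genes, where 14 had an unadjusted p under 0.05; a Nfasc exon on chromosome 1 (132588074 to 132588310) had a share of 69.7% in control and 19.01% in KCl. Adjusted over the list alone, 3 of 50 events were called among ion channels. In the same way 3 of 12 were called among stress and RNA quality genes (stress genes below) and 3 of 19 among imprinted genes. The leading events of both these lists were those of Meg3, which they share. Among late activity-regulated genes 1 of 12 was called in this way, a Homer1 exon with 86.5% in control and 42.1% in KCl, and among glycolysis genes 1 of 13, the Pkm event. In the other lists with a tested event the count adjusted over the list alone was 0: neurexins and neuroligins (25 events, 6 at an unadjusted p under 0.05), glutamate receptors and scaffolds (38, 7), splicing regulators (142, 5), H3K9 methylation genes (59, 3), immediate early genes (6, 0), astrocyte markers (10, 1), oligodendrocyte markers (5, 0), microglia and vascular markers (1, 0), progenitor markers (8, 0), excitatory neuron markers (4, 0), inhibitory neuron markers (3, 1), cholesterol synthesis (10, 0), zinc finger genes (173, 7) and housekeeping genes (13, 0).

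The deposited tables also hold the authors' own test of each KCl library against the control of the same replicate number. Their FDR was under 0.05 in 440 events of replicate 1 and in 188 of replicate 2. Among the 11814 events identifiable in both tables these were 342 and 152, of which 122 were in both, against 4.4 expected of independent lists. That expectation takes every event as equally likely to pass, while events with many reads can be favoured in both tables. Of the 122, 121 had the same direction, 47 with higher and 74 with lower inclusion in KCl. The 90-base exon of Nrxn2 had FDRs of 0 and 1.77e-05 in replicate 1 and replicate 2, with a higher share in KCl in both, and the Nrxn2 exon at 6488784 had 0.125 and 0.0375. Each such test compares a library with a library on their reads and does not compare the conditions, and events of a gene share reads.

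The number of splicing events of each type was compared between groups. Both libraries of a replicate number are listed with the same events, 19447 in replicate 1 and 22703 in replicate 2, so the listed numbers cannot differ between groups. With at least 1 read of each form required, a setting chosen after the tables were seen, cassette exons made up 67.4% ± 1.05 (SD, n = 2) of events in control and 66.7% ± 0.61 in KCl (2-sided exact permutation test, p = 0.667; the smallest p that 2 against 2 allows is 0.333).

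Transcript abundance was read from the best-covered event of each gene, since the tables hold no value per gene; such a value mixes abundance with event coverage. No gene passed edgeR's test without a replicate block. CPM here are reads of the best-covered events, scaled to their TMM-adjusted total in the library. Tagln had 439 ± 47.7 CPM (SD, n = 2) in control and 2439 ± 439 in KCl, a log2 fold change of 2.48 (SE 0.41). Psd had 711 ± 303 and 129 ± 40.6, a log2 fold change of -2.46 (SE 0.50), and Unc5a had 56.2 ± 8.18 and 8.46 ± 3.25, a log2 fold change of -2.71 (SE 0.53). edgeR called 0 of 6114 genes, with a smallest adjusted p of 0.352, and 750 had an unadjusted p under 0.05 (302 higher, 448 lower), against 306 expected by chance. DESeq2 called 70 and limma 0. With the replicate number as a block edgeR called 1259 genes (541 higher, 718 lower), and the deviations of same-numbered libraries correlated at 0.623, so the count of 0 depends on leaving the block out. The edgeR count without a block was 302 without KCl replicate 2, 24 without control replicate 2, 3 without KCl replicate 1 and 0 without control replicate 1, so it depended on which libraries entered. Groups did not overlap in 43.3% of genes, against 33.3% by chance.

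Further genes with the smallest p and higher values in KCl were Bcas1 (43.1 CPM in control and 357 CPM in KCl), Clcf1 (21.5 and 130), Mbp (35.9 and 156), Col11a1 (67.0 and 270) and Aebp1 (7.51 and 36.6). Of low abundance were Gm12925 (1.77 and 22.1), Adamtsl5 (1.15 and 14.3) and Uba7 (0.97 and 10.1). Lower in KCl were B4galnt1 (240 and 53.4), Slc2a6 (91.9 and 17.1), Dmtn (205 and 29.8), Bend6 (429 and 62.2), Kifc2 (322 and 42.3), Atp2b3 (77.8 and 14.9), Cacna1i (20.2 and 1.47) and Scn1a (17.3 and 1.19). Nrxn2 stood at 872 and 450 (edgeR adjusted p 0.389) and Nrxn3 at 124 and 55.4 (0.543). For the events themselves, edgeR called 0 of 11814 event levels, with 1291 at an unadjusted p under 0.05; DESeq2 called 101, limma 0 and edgeR with the block 1359. Without KCl replicate 2 edgeR called 434 event levels, without control replicate 2 it called 80, without control replicate 1 it called 3 and without KCl replicate 1 it called 0.

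The ion channel list had a median log2 change of -1.65 (16 of 16 genes lower in KCl), which did not pass in fry, or in camera with an estimated correlation (below). Glutamate receptors and scaffolds had a median of -1.50 (19 of 21 lower) and cholesterol synthesis genes a median of -1.65 (8 of 8 lower). Oligodendrocyte markers had a median of 1.91 (5 of 5 higher). Over all genes tested 0 were called by edgeR in any list; adjusted over the list alone, 8 of the ion channels, 9 of the glutamate genes, 7 of the cholesterol genes, 3 of the oligodendrocyte markers and 1 of 2 microglia and vascular markers were called, and 0 in each other list. The set test fry, which asks whether a list moves on balance in 1 direction, gave no adjusted p under 0.245. The set test camera gave adjusted p of 0.417 or more for every list with the correlation estimated from these libraries, so none passed. That setting weakens the test itself: for oligodendrocyte markers, at an estimated correlation of 0.026, its unadjusted p went from 3.33e-06 to 0.0456. For other lists the estimates lay far above the preset of 0.01, so the preset can overstate their evidence. They were 0.427 for glutamate genes, 0.727 for ion channels and 0.713 for cholesterol synthesis. With 4 libraries camera cannot decide whether its calls at a preset correlation of 0.01 hold. At that preset its adjusted p was 2.93e-11 for glutamate genes, 2.93e-11 for ion channels, 5.29e-08 for cholesterol synthesis, 0.00962 for neurexins and neuroligins, 0.00962 for late activity-regulated genes and 0.0241 for other adhesion genes, all downward. It gave 1.66e-05 for oligodendrocyte, 0.00982 for astrocyte, 0.0123 for microglia and vascular and 0.0297 for progenitor markers, all upward. The 2 microglia and vascular genes measured were Col1a2 and Pdgfrb, so no marker of microglia was measured.

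The median log2 changes of the remaining lists were -1.06 for neurexins and neuroligins (6 genes), -0.45 for other adhesion genes (17), -0.57 for late activity-regulated genes (7), -0.64 for immediate early genes (5), -0.84 for stress genes (3), -0.50 for glycolysis genes (7) and -0.32 for imprinted genes (8). They were 0.92 for astrocyte markers (6), 1.72 for microglia and vascular markers (2), 0.75 for progenitor markers (7), 0.24 for splicing regulators (52), 0.20 for H3K9 methylation genes (26), 0.23 for housekeeping genes (10) and 0.06 for zinc finger genes (122). Of the neuron markers, those of inhibitory neurons had a median of -0.996 (2 genes, Gad1 and Lhx6) and those of excitatory neurons -0.08 (2 genes, Cux1 and Cux2).

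**Figure D2:**
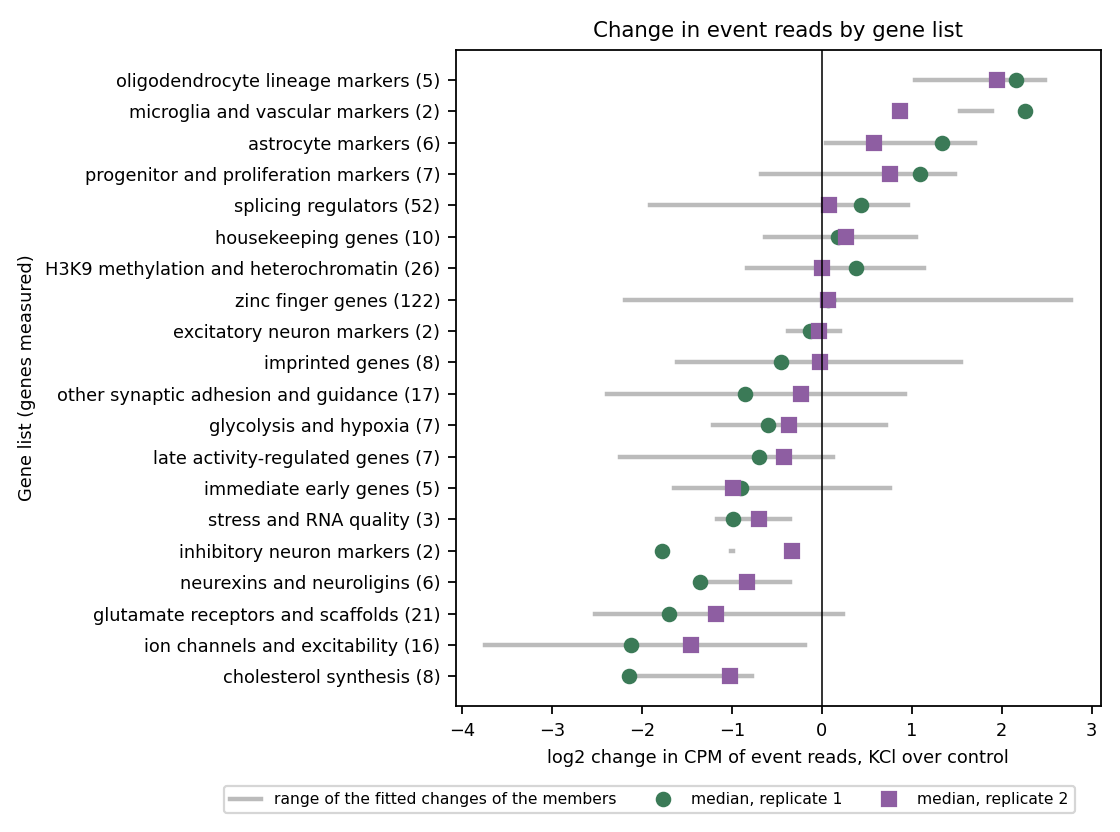
Log2 change in CPM of event reads, KCl over control, by gene list, with the number of genes measured in brackets; circles and squares are list medians in replicate 1 and replicate 2, and grey lines span the fitted changes of the members. The ion channel medians lie at -2.12 and -1.45 and the oligodendrocyte medians at 2.16 and 1.95. No list passed fry, or camera with an estimated correlation, which is a weak test with 4 libraries.

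The ChIP libraries address whether an enriched cage leaves a lasting change in H3K9me3. Gene by gene the libraries were close: over 23494 genes the SD of the log2 ratio to the home cage was 0.29 in enriched replicate 1 and 0.35 in enriched replicate 2, and it was 0.31 between the enriched libraries. The limma test with voom weights called 1 gene, with 461 at an unadjusted p under 0.05 against 1175 expected by chance. The gene was Rpl3l on chromosome 17 (24727826 to 24736143), with 3 fragments in the home cage and 37 and 21 in the enriched libraries, a ratio of 5.56 (1.81 to 27.8) and a limma adjusted p of 0.0229. It lies under the 50 fragments set for naming a gene and was chosen after its values were seen. It was not called with scaling by the median of ratios, with libraries thinned to the lowest depth, or with another minimum. Over 231241 windows of 10 kb limma called 2, with 11173 at an unadjusted p under 0.05 against 11562 expected by chance. Both were higher in the enriched libraries: chromosome 5 from 92420001 (2, 47 and 29 fragments, ratio 10.9, 2.92 to 91.9) and chromosome 1 from 160430001 (3, 43 and 46 fragments, ratio 8.53, 2.83 to 42.2), also singled out after their values were seen. Most windows at an unadjusted p under 0.05 in limma were lower in the enriched libraries, opposite to the 2 called windows. The home-cage library has no replicate and is assumed to vary like the enriched libraries.

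Of genes with at least 50 fragments on average, none passed. Those with the smallest p and higher values in both enriched libraries were Fam219a (log2 ratio 0.83, SE 0.27), Gk (0.92), Ttl (0.92), Ppp1r2 (1.08), Plekhg3 (0.67), Smad7 (0.93), Per3 (0.74), Sox10 (1.11), Arid1b (0.39) and Akap8l (0.91). Those with lower values in both were Fsip2l (-0.76, SE 0.25), Cldn34d (-0.54), Sfi1 (-0.21), Pramel15 (-0.83), Tnfrsf23 (-0.81), Upp1 (-0.72), Zfp647 (-0.72), Ttpa (-0.72), Ms4a12 (-0.74) and D6Ertd527e (-0.76). Each had a limma adjusted p of 1.

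Over clustered protocadherins the signal was 3.47 times the library's background (3.43 to 3.51) in the home cage, 3.91 times (3.88 to 3.94) in enriched replicate 1 and 2.96 times (2.93 to 2.99) in enriched replicate 2. Intervals of a class come from its pooled fragments, while its value is a mean over genes. Overlapping gene models count a fragment more than once, so these intervals can understate even the counting error. Zinc finger genes had 1.61, 1.71 and 1.52 times, olfactory receptors 1.80, 1.93 and 1.46 times, and vomeronasal receptors 1.32, 1.39 and 0.94 times. Housekeeping genes, as the background class, had 0.55 (0.49 to 0.61), 0.65 (0.60 to 0.70) and 0.70 (0.64 to 0.77) times. Enriched replicate 2 lay below both other libraries in those 4 classes and in inhibitory neuron markers (2.965, 3.125 and 2.788 times). It was also lowest in imprinted genes (1.478, 1.495 and 1.395 times) and late activity-regulated genes (1.254, 1.259 and 1.207 times). It lay between them in excitatory neuron (1.715, 1.95 and 1.872 times), oligodendrocyte, microglia and vascular, and progenitor markers. In the other lists it lay above both, as in splicing regulators (0.742, 0.782 and 0.893 times) and immediate early genes (1.118, 1.178 and 1.511 times). No input library was used here.

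**Figure D3:**
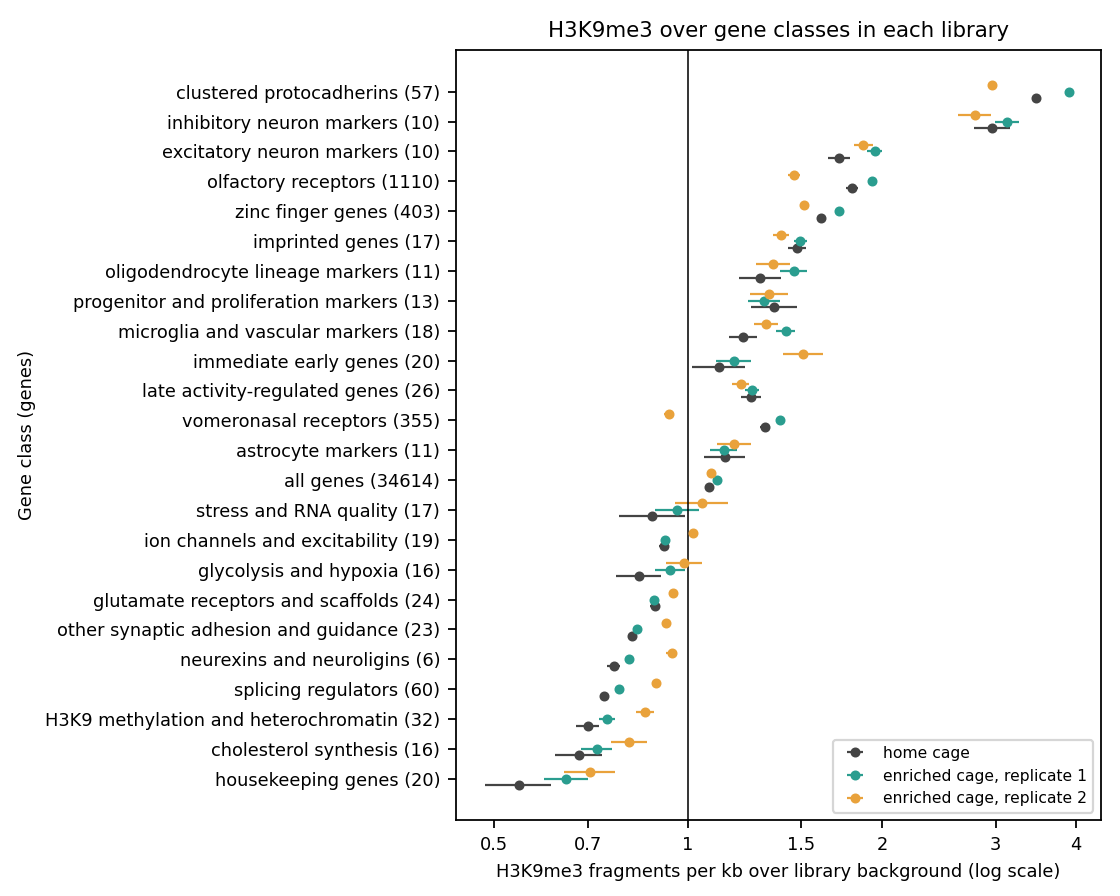
H3K9me3 fragments per kb over the library's background, on a log axis, by gene class with the number of genes in brackets. Points are libraries, and bars are 95% Poisson intervals of the class's pooled fragments, scaled to the mean over genes. Clustered protocadherins lie highest, at 3.47, 3.91 and 2.96 times background, and housekeeping genes lowest.

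Over Nrxn2 and Nrxn3 H3K9me3 stood near background and did not differ detectably. Nrxn2 (chromosome 19, 6418756 to 6533217) had 0.977 times background (0.859 to 1.107) in the home cage, 1.075 (0.988 to 1.167) in enriched replicate 1 and 1.185 (1.073 to 1.306) in enriched replicate 2, a log2 ratio of 0.19 (SE 0.18). Nrxn3 (chromosome 12, 88722701 to 90334935) had 0.905 (0.874 to 0.937), 0.891 (0.870 to 0.913) and 0.930 (0.903 to 0.958), a log2 ratio close to 0 (SE 0.09), each with a limma adjusted p of 1. Within 1 kb of the 90-base exon of Nrxn2 there were 11 fragments in the home cage and 7 and 7 in the enriched libraries, a ratio of 0.37 with a counting interval of 0.15 to 0.89. Around the 90-base exon of Nrxn3 there were 2, 7 and 1 fragments, a ratio of 1.15 (0.23 to 11.1). The other exons of these genes had ratios from 0.74 to 5.47, the latter at the Nrxn2 exon at 6519249 (0.869 to 227), each with an interval that includes 1. In all 18 exons had been looked at, so the low ratio is 1 of many, and the intervals make no allowance for spread between animals.

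Across the gene lists limma called 0 genes in any list, over all genes or adjusted over the list alone, and fry gave no adjusted p under 0.774. Camera with the preset correlation of 0.01 gave adjusted p of 0.00194 for H3K9 methylation genes (median log2 ratio 0.18), 0.00435 for splicing regulators (0.11) and 0.00751 for immediate early genes (0.31), upward, and 1.32e-07 for vomeronasal (-0.17) and 0.0391 for olfactory receptors (-0.10), downward. With an estimated correlation every adjusted p was 0.952, so none passed. That setting weakens the test itself: for imprinted genes, at an estimated correlation of 0.011, camera's unadjusted p went from 0.0742 to 0.327. For the lists called at the preset the estimates lay far above 0.01, so the preset can overstate their evidence. They were 0.823 for vomeronasal and 0.66 for olfactory receptors, 0.392 for H3K9 methylation genes, 0.367 for splicing regulators and 0.289 for immediate early genes. With 3 libraries camera cannot decide whether the calls at the preset hold. In enriched replicate 1 the vomeronasal median was 0.09 and in enriched replicate 2 -0.49, so the downward medians of both receptor lists came from enriched replicate 2; the olfactory medians were 0.14 and -0.32. The upward medians were also larger in enriched replicate 2 than in enriched replicate 1: 0.282 and 0.126 for H3K9 methylation genes, 0.261 and 0.048 for splicing regulators, and 0.493 and 0.238 for immediate early genes. The other medians lay between -0.10 for progenitor markers and 0.18 for housekeeping genes. Median and fry direction differed in sign for late activity-regulated genes, inhibitory neuron markers and stress genes, and median and camera direction for the first pair, for astrocyte markers, for stress genes and for zinc finger genes, all with medians between -0.06 and 0.06.

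Whether genes of the splicing comparison were those with more H3K9me3 was tested by their overlap. Of the 200 genes with the smallest splicing p, 108 (54.0%) had higher H3K9me3 in both enriched libraries, against 50.2% of the other genes, over 4591 genes measured in both assays (odds ratio 1.16, 2-sided Fisher's exact test, p = 0.312). In the same exact test the odds ratio was 1.22 with 500 genes (p = 0.0415) and 1.49 with 100 genes (p = 0.055). The assays differ in tissue, stimulus and time, and genes are not independent replicates.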

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

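The comparison of mitochondrial fragments was chosen after the data were examined. Reads from mitochondrial DNA, which carries no histones, lie outside the regions compared in the ChIP libraries. Scaled to the fragments of the library, they came to 341 CPM (326 to 355) in the home cage, 1099 CPM (1081 to 1118) in enriched replicate 1 and 383 CPM (370 to 397) in enriched replicate 2. Both enriched libraries lay above the home-cage library, which is why they are given here, and they differed more from each other than enriched replicate 2 did from the home cage. Intervals cover counting error only, no input library was used here, and no explanation was tested.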

How the results depend on the processing

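Added after the data were seen were DESeq2 for levels, limma with pseudocount 0.5 or 1, summing events of equal coordinates, and requiring reads of both forms. Of 63 recomputed summary values, 37 were classed as the same in direction and side of the threshold. A further 16 became stronger, 9 weaker and 1 moved beyond its interval. The 37 include the settings for the number of splicing events by type. Their values ran from -0.672 to 0.599 against 0 in the main setting, so they kept no direction. Of 2173 values for named items and gene classes, 1986 were classed as the same and 135 newly passed the threshold. Of the rest, 42 without a test moved beyond their interval or standard error and 10 reversed.

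With the replicate number as a block, edgeR called 167 splicing events (61 higher, 106 lower), 1359 event levels and 1259 genes, against 0 each without it. The deviations of same-numbered libraries correlated at 0.081 for splicing and 0.623 for gene levels. With the block the common dispersion fell from 0.153 to 0.0402 for gene levels and from 0.0941 to 0.0494 for splicing. Libraries of the same number thus deviated together in gene levels, and the fit without the block takes no account of it. The labels do not say what a number shares and there are only 2 pairs, so a pairing by design is not shown. DESeq2 called 11 splicing events, 101 event levels and 70 genes. Splicing calls stayed at 0 under every other setting run: each limma setting, no filter, a mean of at least 5, centred libraries, absent events as 0, summed events, and each library left out. Leaving out each library in turn, with the lone library assumed to vary like the others, gave 0 to 434 event levels and 0 to 302 genes. The cause of these changes was not tested. For the cassette exon share it gives -0.599 to 0.599 percentage points by construction, as both libraries of a number list the same events, and so tests nothing. Requiring reads of both forms gave -0.672, and requiring 1 read moved nothing.

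The 1 gene called for H3K9me3 became 0 with the median of ratios, thinning, a minimum of 50 and no minimum, and 5 with an eBayes trend (4 higher, 1 lower). A minimum of 50 removes Rpl3l by construction. The 2 windows became 1 with every read, 6 with scaling by total, 8 with the median of ratios, 3 with an eBayes trend, and 0 with thinning, a minimum of 50, no minimum and 50 kb windows. For the others the cause was not tested. With the genome mean as background the zinc finger enrichment of the home cage was 1.56 in place of 1.61, as the mean exceeds the median. The odds ratio of the overlap was 1.22 with 500 genes, past 0.05, and 1.49 with 100.

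Signs reversed, with the cause not tested, in items near 0 or with few reads. In log2 odds, the Col1a2 intron went to 0.001 with pseudocount 0.1. Leaving out each library in turn gave -1.65 to 1.66 for that intron, above 0 without control replicate 2. In Nrxn2 it gave -2.38 to 0.42 for the A5SS event and -0.19 to 3.05 for the exon at 6448255, each reversed without control replicate 2. It gave -0.90 to 1.72 for the MXE event and -1.73 to 0.895 for the exon at 6450531, each reversed without KCl replicate 2. The level of Cux1 ranged from -0.10, without KCl replicate 2, to 0.43. H3K9me3 over Nrxn3 went to 0.03 with scaling by total, 0.019 with thinning and 0 with an eBayes trend.

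Not run were a mapping score of at least 30, which the files lack, and 2 kb around gene starts, which needs strand.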

Other observations

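Apart from the test of mixed transcripts, which was written before its result was seen, the tests in this part were chosen after the results they address had been seen. Each pattern was found and tested on the same data, so the explanations are hypotheses. Intervals in this part are taken over genes or gene classes, which are not independent replicates. They do not measure the spread between cultures or animals.

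In the KCl cultures more splicing events and gene levels than expected by chance had an unadjusted p under 0.05 (929 against 504 and 750 against 306), though edgeR called none without a replicate block. Whether the 2 go together was not tested. A difference in depth is argued against, since KCl over control event reads were 1.02 in replicate 1 and 0.867 in replicate 2. A lower share of neurons may contribute: markers of other cell types exceeded neuron markers by 2.65 (1.16 to 3.68) in log2 in replicate 1 and by 1.08 (0.56 to 1.45) in replicate 2, and the 4 other lists did not move apart beyond their spread (largest gap 0.84, -0.21 to 1.89). Only 4 neuron markers were measured, though, and they did not fall alike: the inhibitory pair had a median of -0.996 and the excitatory pair -0.08, with Cux1 at 0.205 and Cux2 at -0.372. Against 37 receptor, scaffold and channel genes the excess was 3.51 (2.47 to 4.16) and 2.07 (1.69 to 2.52), but these lists were taken for it after their fall was seen, and neurons may regulate such genes themselves. Whether splicing shifts come from mixing neuronal and other transcripts cannot be told apart from changes within cells: the shared splicing change in genes that fell over 4-fold was 1.05 times that in genes within 2-fold, with an interval of 0.01 to 2.17. An effect of depolarization on the cells, which the design names, stays open beside it.

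Enriched replicate 2 had a flatter H3K9me3 profile than the other libraries. Over the gene classes the slope of its log2 enrichment on that of the others was 0.76 (0.66 to 0.86), against 1 (0.95 to 1.05) for enriched replicate 1 on the home cage. A weaker pull-down would give such a slope and is a candidate explanation. Shrinkage toward background alone does not cover every class. Immediate early genes stood at 1.118 times in the home cage, 1.178 in enriched replicate 1 and 1.511 in enriched replicate 2. Vomeronasal receptors stood at 1.317, 1.389 and 0.936 times. An effect of the enriched cage on marked regions cannot be told apart from differences between samples: enriched replicate 1 lay above the home cage in 4 of the 4 marked classes, but in 0 of 4 by more than the SD between the enriched libraries, and the home cage has 1 library. Other differences between the mice or the libraries stay open.

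Fragments on chromosome Y came to 1911 CPM of all fragments in the home cage, 1914 CPM in enriched replicate 1 and 986 CPM in enriched replicate 2. Chromosome X held 192440 of 6187183 fragments in the home cage, 394222 of 13008585 in enriched replicate 1 and 231254 of 8058257 in enriched replicate 2. The share on chromosome X was thus not higher in enriched replicate 2. No explanation of the lower chromosome Y value was tested.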
